A study of Homo sapiens with 48 samples.

How the data were processed

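RNA was measured in 48 libraries of Jurkat cells, in 12 groups (6 treatments at 2 times) of 4 libraries each. Per the labels' protocols, cells were grown in RPMI medium, total RNA was isolated with RNeasy Plus kits and an on-column DNase step, checked on a TapeStation, and made into mRNA libraries with the NEBNext Ultra RNA kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with Trimmomatic, aligned to hg38 with STAR and counted per gene with HTSeq, and no versions are given. The deposited values are raw counts per gene as HTSeq made them, per the submitters' processing notes, and the deposited table also carries each gene's position, length and strand. The strand setting of the counting is not given in the sources used here. Nothing in these sources says that the replicates were separate cultures, so the p-values measure the spread between these samples, which in part may be technical.

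Library columns were matched to the labels by name, and 3 columns that matched no label were not used. The table held 60279 genes, of which 40995 were named from the gene name table, 15595 from GENCODE release 29 and 3689 kept their identifier. Of the identifiers in that release 93.56 percent had the same coordinates there. Library totals were 6709264 to 7728038 counts, with 12605 to 13676 genes at 10 counts or more and between 0.976 and 3.66 percent of counts from the mitochondrial genome. A count of 0 allows up to 3 counts, or 0.447 CPM in the smallest library.

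Genes were kept by edgeR's filterByExpr with the groups, libraries were scaled with TMM factors, and genes were tested with edgeR's quasi-likelihood F test with robust dispersions and Benjamini-Hochberg adjustment within each comparison at 0.05. One model was fitted per time over 24 libraries, and time differences were fitted over all 48. This gave 21 comparisons. Of 39 gene lists fixed before the data were examined 35 could be tested, with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, and the other 4 are marker lists of other cells with fewer than 3 genes measured. The comparisons, main tests, rule for named genes and first set of alternatives were also fixed before the data were examined. CPM values of genes use library totals multiplied by their TMM factors, and the limit for a count of 0 uses totals alone.

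Named genes followed a fixed rule. The first part takes the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 CPM and, between 2 groups, no overlap of libraries, passing over clone identifiers and pseudogenes. The second takes up to 4 members with the smallest adjusted p of each called list or list with 3 called members. The third always takes ATF4, DDIT3, ATF3, ASNS, TRIB3, CHAC1, HSPA5, HMOX1, NQO1, TXNIP, MYC and MT-ND1.

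At 1 h libraries with the same replicate number deviated together. The correlation of their deviations was above 0.1 in each of the 15 pairs of groups, from 0.584 to 0.727 with a median of 0.685. A fit with the replicate number as a block is therefore given beside the main one. Much of this correlation can come from replicates 1 and 2 parting from 3 and 4. The component separating them held 68.1 percent of the variance of the deviations at 1 h, and the next held 4.3 percent. Of 24 libraries 18 correlated best with their own number, so pairing by single numbers is less certain than that split. The block comes from the data, since no label explains the numbers.

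The method was tested on simulated data with 200 changed genes. For a 24 h comparison of 2 groups it recovered 65.7, 92.5 and 100 percent of genes changed 1.25, 1.5 and 2-fold, with 6.4 percent false among its calls. For a 24 h interaction it recovered 32.8, 74.6 and 92.4 percent, with 5.5 percent false. At 1 h it recovered 29.9, 68.7 and 97 percent without the block (0.7 percent false) and 73.1, 97 and 100 percent with it (8.8 percent false). There a difference between replicates 1 and 2 and replicates 3 and 4 was simulated (SD 0.25 on the log2 scale), the same in every treatment. In the data piericidin at 1 h called 1 gene in replicates 1 and 2 alone and 360 in replicates 3 and 4 alone. The rates at 1 h may therefore not carry over to the data. A shifted list was recovered in each case with 0 other lists called by camera. Simulated genes varied independently of each other, so this does not test list calls where genes of a list vary together.

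The alternatives of the first set were RLE factors, no filter on low counts, DESeq2, a replicate block, a fit with only the groups compared, leaving out each library, and camera with an estimated correlation. After seeing the data, fits of replicates 1 and 2 only and of replicates 3 and 4 only at 1 h, the alternatives on the blocked 1 h fits, and fits without antimycin 24 h libraries 3 and 4 were added. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.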

Results

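RNA sequencing measured transcript levels in Jurkat cells, a human T-cell acute lymphoblastic leukaemia line, after 1 h or 24 h in 6 treatments. Cells received vehicle (DMSO and alcohol), 400 µM mitoTEMPO (an antioxidant that accumulates in mitochondria), 1 µM piericidin (an inhibitor of respiratory complex I), 1 µM antimycin (an inhibitor of complex III), or mitoTEMPO together with either inhibitor. Each of the 12 groups held 4 libraries, 48 in all. The deposited table gave whole counts per gene for 60279 genes, of which 38014 had a count in some library. Library totals ran from 6709264 to 7728038 counts, and a count of 0 allows a level of up to 0.447 CPM (counts scaled to library size). The series title concerns how cell fitness depends on reactive oxygen species from mitochondria. The comparisons therefore asked which transcripts moved when complex I or complex III was blocked, which moved with the antioxidant alone, and whether the antioxidant altered the response to each inhibitor. Changes are given as fold or as log2 change ± standard error (SE), with n = 4 per group. The SE of a gene's log2 change is its absolute value divided by the square root of edgeR's F statistic. That statistic pools the spread over all libraries of the fit. Adjusted p is from edgeR within a comparison or, for gene lists, from camera over lists. Genes given by name and lists said to have risen or fallen kept their call in every alternative tried unless a sentence says otherwise. Estimated correlations and, at 1 h, fits of 2 of the 4 replicates are left aside in this statement. Counts of list members past the threshold were not rechecked in the alternatives, except where a sentence gives them. Gene positions are on build hg38, as in the deposited table.

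After 24 h of piericidin, genes of the integrated stress response, in which the transcription factor ATF4 raises amino acid supply, rose together. CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956519), rose 3.64-fold, from 3.76 ± 0.343 to 13.8 ± 3.31 CPM (mean ± SD, n = 4; log2 1.87 ± 0.25 SE, adjusted p = 2.73e-05). STC2, a secreted glycoprotein (ENSG00000113739, chromosome 5, 173314713 to 173329503), rose 2.57-fold (1.36 ± 0.08, adjusted p = 2.27e-20), and ASNS, asparagine synthetase (ENSG00000070669, chromosome 7, 97852118 to 97872542), rose 2.45-fold, to 39.2 ± 3.15 CPM (1.29 ± 0.10, adjusted p = 3.15e-13). ATF4 itself (ENSG00000128272, chromosome 22, 39519695 to 39522685) rose 1.38-fold (0.46 ± 0.04). ASS1, argininosuccinate synthetase of arginine synthesis, rose 2.68-fold (1.42 ± 0.10), and SPNS3 and the peptide hormone gene ADM2 rose 2.51-fold and 2.46-fold. The steepest fall was in TXNIP, an arrestin-family protein that restrains glucose uptake and binds thioredoxin (ENSG00000265972, chromosome 1, 145992435 to 145996600). It fell to 0.288 of its vehicle level, from 41.9 ± 1.74 to 12.1 ± 1.34 CPM (−1.80 ± 0.10, adjusted p = 6.15e-22). Its relative ARRDC4 fell to 0.536 (−0.90 ± 0.09).

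Of the 19 measured members of the integrated stress response list, 16 rose and none fell with piericidin at 24 h (18 rose adjusted over the list alone), with a median log2 change of 0.76 (adjusted p = 6.64e-60, and 2.69e-05 with an estimated correlation). GPT2, a mitochondrial alanine aminotransferase, rose by 0.76 ± 0.07, the transcription factor ATF3 by 1.07 ± 0.22 and the ATF4 antagonist TRIB3 by 0.53 ± 0.08. DDIT3, the transcription factor CHOP, had a log2 value of 0.04 ± 0.15 (adjusted p = 0.913). Among amino acid transporters 9 of 11 rose (9 adjusted over the list alone; list adjusted p = 6.98e-20, and 0.0104 with an estimated correlation), led by the glycine transporter SLC6A9 at 3.07-fold (1.62 ± 0.22), with SLC1A5 at 1.37-fold and SLC38A2 at 1.3-fold. Among 12 serine and one-carbon genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 9.28e-05, and 0.124 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, rose 1.62-fold, PSAT1 1.61-fold and MTHFD2 1.32-fold, while the mitochondrial folate carrier SLC25A32 fell to 0.833. Of 20 cytosolic tRNA synthetases 8 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p = 0.000138, and 0.255 with an estimated correlation), with MARS1 at 1.36-fold and CARS1 at 1.42-fold.

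Cholesterol synthesis was the second large group to rise with piericidin at 24 h. Of 23 measured members 16 rose and none fell (18 adjusted over the list alone), with a median of 0.25 (adjusted p = 1.09e-24, and 1.03e-05 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate (ENSG00000112972, chromosome 5, 43289395 to 43313512), rose 1.49-fold, from 111 ± 9.29 to 165 ± 9.47 CPM (0.57 ± 0.05). The sterol-sensing transcription factor gene SREBF2 rose 1.32-fold and MSMO1 1.39-fold. In fatty acid synthesis 4 of 10 rose (6 adjusted over the list alone; adjusted p = 1.6e-05, and 0.0165 with an estimated correlation), including the desaturase genes FADS2 at 1.26-fold and FADS1 at 1.17-fold.

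Lists of growth and mitochondrial translation fell by smaller amounts. In ribosome biogenesis 8 of 22 fell and none rose (15 fell adjusted over the list alone; median −0.12, adjusted p = 4.23e-11, and 0.0224 with an estimated correlation), with the nucleolar genes LYAR at 0.822 of vehicle and NPM1 at 0.848. Of 51 mitochondrial ribosome genes 6 fell (10 adjusted over the list alone; median −0.10, adjusted p = 2.96e-08, and 0.0462 with an estimated correlation), such as MRPL1 at 0.788 and MRPL3 at 0.856. Nucleotide synthesis had 3 of 16 lower (8 adjusted over the list alone; adjusted p = 3.62e-05, and 0.0419 with an estimated correlation), including PAICS at 0.88. Mitochondrial chaperones and proteases had 4 of 13 lower (6 adjusted over the list alone; adjusted p = 0.00114, and 0.0205 with an estimated correlation), HSPE1 among them at 0.878. Mitotic genes had 4 of 21 lower (10 adjusted over the list alone; adjusted p = 9.25e-05, and 0.124 with an estimated correlation), with AURKA at 0.863. The unfolded protein response of the endoplasmic reticulum (ER) was split: EDEM1, HERPUD1 and ERN1 rose, HSPA5, the ER chaperone BiP, fell to 0.881 (−0.18 ± 0.04, adjusted p = 0.0024), and its list gave no call (adjusted p = 0.852, median −0.01, mean 0.04). Glycolysis gave none either (adjusted p = 0.373, median −0.03, mean 0.04, test direction down), with ALDOC higher at 1.57-fold and LDHA lower at 0.843.

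In all, 467 genes rose and 577 fell with piericidin at 24 h among 13555 tested, of which 86 and 10 changed by more than 1.5-fold. Values that did not pass were 0.21 ± 0.15 for NQO1 (adjusted p = 0.45), −0.01 ± 0.04 for MYC (adjusted p = 0.895) and 0.09 ± 0.10 for MT-ND1 (adjusted p = 0.649), and HMOX1 had too few counts to test. The count of 1044 became 637 without piericidin library 4, 687 without vehicle library 1 and 1612 when only the groups compared were fitted. Calls for the TCA cycle (4 of 22 lower), complex III (1 of 9), complexes IV and V (1 of 25) and DNA replication lists (2 of 21) were lost with an estimated correlation (adjusted p = 0.298 to 0.483) and without piericidin library 2 (adjusted p = 0.0603, 0.0603, 0.0748 and 0.0631), the TCA cycle also without vehicle library 3 (adjusted p = 0.0704).

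**Figure D1:**
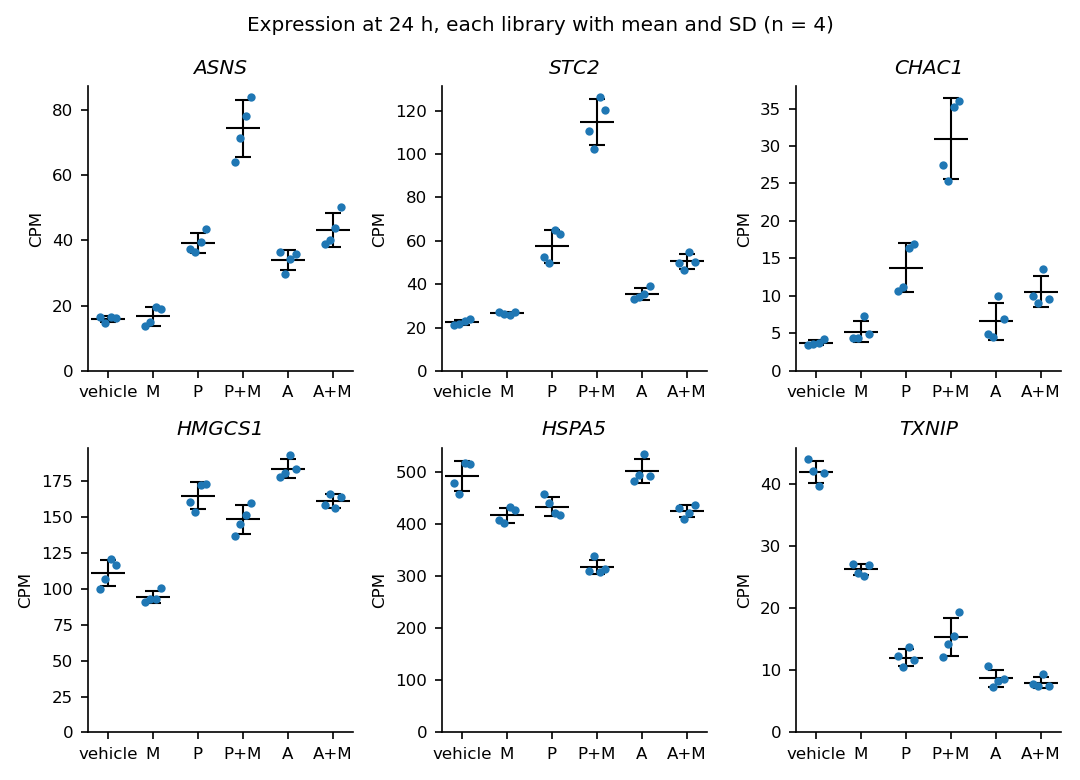
CPM of 6 genes in each 24 h library (circles), with the mean and SD of the 4 libraries per treatment (x axis: vehicle, mitoTEMPO (M), piericidin (P), antimycin (A) and combinations; y axis: CPM). ASNS averaged 39.2 CPM with piericidin and 74.3 with piericidin and mitoTEMPO, while TXNIP averaged 41.9 CPM in vehicle and 12.1 with piericidin.

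Antimycin for 24 h moved many of these groups. ASS1 rose 2.51-fold (1.33 ± 0.10), ASNS 2.13-fold (1.09 ± 0.11, adjusted p = 1.5e-10), and PCK2, mitochondrial phosphoenolpyruvate carboxykinase, 2.02-fold (1.02 ± 0.12). TXNIP fell to 0.208 of vehicle, at 8.70 ± 1.39 CPM (−2.27 ± 0.11, adjusted p = 7.08e-26), and ARRDC4 fell to 0.504. VEGFA, a vascular growth factor induced by low oxygen and by ATF4, rose 1.77-fold (0.83 ± 0.12), although its list of hypoxia-inducible factor targets had 1 of 15 higher and a call (adjusted p = 0.0467, and 0.0869 with an estimated correlation) that was lost without antimycin library 2 (0.078), 3 (0.103) or 4 (0.0557) and vehicle library 1 (0.129), 2 (0.0636) or 4 (0.058). MT-CO2, the mitochondrially encoded subunit of cytochrome c oxidase (ENSG00000198712, mitochondrial genome, 7586 to 8269), rose 1.86-fold, from 1139 ± 76.4 to 2118 ± 124 CPM (0.90 ± 0.10, adjusted p = 2.31e-05).

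By list, cholesterol synthesis had the lowest adjusted p with antimycin: 15 of 23 rose and none fell (17 adjusted over the list alone; median 0.27, adjusted p = 2.28e-45, and 9.74e-08 with an estimated correlation), with HMGCS1 at 1.66-fold (0.73 ± 0.05), MSMO1 at 1.53-fold and FDFT1 at 1.35-fold. In the integrated stress response 11 of 19 rose (14 adjusted over the list alone; median 0.50, adjusted p = 1.29e-32, and 0.0012 with an estimated correlation), with STC2 at 1.59-fold, ADM2 at 1.92-fold and ATF4 higher by 0.32 ± 0.04 on the log2 scale. Amino acid transporters had 7 of 11 higher (8 adjusted over the list alone; adjusted p = 4.14e-15, and 0.0207 with an estimated correlation), with SLC1A5 at 1.27-fold. Fatty acid synthesis had 3 of 10 higher (4 adjusted over the list alone; adjusted p = 4.77e-09, and 0.00173 with an estimated correlation), with FADS2 at 1.3-fold and SCD at 1.18-fold. Of the 13 mRNAs encoded by mitochondrial DNA (mtDNA) 5 rose (12 adjusted over the list alone; median 0.35, adjusted p = 7.61e-18, and 0.0409 with an estimated correlation). Targets of the antioxidant regulator NRF2 had 4 of 16 higher (10 adjusted over the list alone; adjusted p = 6.35e-08, and 0.0409 with an estimated correlation). Of 21 mitotic genes 2 were lower (3 adjusted over the list alone; adjusted p = 5.83e-05, and 0.0991 with an estimated correlation), with HMMR at 0.83.

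Antimycin raised 218 genes and lowered 78 at 24 h, 30 and 5 of them by more than 1.5-fold. Libraries 3 and 4 of this group stood apart from libraries 1 and 2: list medians differed between the pairs by 0.19 for the integrated stress response, 0.11 for cytosolic ribosomal proteins and −0.12 for mtDNA-encoded mRNAs. Without libraries 3 and 4, a choice made after seeing the data, 98 genes were higher and 45 lower, 99 of these 143 being in the count of 296. The count was 167 without antimycin library 3, 182 without library 4 and 188 without vehicle library 1. In that smaller set cholesterol synthesis had 11 higher, the integrated stress response 8, mtDNA-encoded mRNAs 3, amino acid transporters 1 and NRF2 targets 0 (by edgeR), and the last 3 lists had adjusted p = 0.0697, 0.203 and 0.279 with an estimated correlation. The lists of tRNA synthetases (6 of 20 higher), serine synthesis (4 of 12) and ribosomal proteins (6 of 49) were called with all libraries and not without these 2 (adjusted p = 0.13, 0.0738 and 0.215), nor with an estimated correlation (0.115, 0.0848 and 0.305). ATF3 rose by 0.80 ± 0.23 (adjusted p = 0.0399) and TRIB3 by 0.31 ± 0.08 (adjusted p = 0.0348). Neither call held without antimycin library 4 (adjusted p = 0.228 and 0.131), vehicle library 2 (0.131 and 0.112) or vehicle library 3 (0.134 and 0.137). ATF3 was also lost without vehicle library 1 (0.0564), TRIB3 without antimycin library 3 (0.131) and vehicle library 4 (0.0738), and their highest adjusted p over all alternatives was 0.228 and 0.431. Below the threshold were CHAC1 (0.81 ± 0.29, adjusted p = 0.16), MT-ND1 (0.36 ± 0.10, 0.0574), NQO1 (0.35 ± 0.15, 0.235), DDIT3 (0.11 ± 0.15, 0.796), HSPA5 (0.03 ± 0.04, 0.828) and MYC (0.03 ± 0.04, 0.843).

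Set against each other at 24 h, the inhibitors differed in 118 genes past the threshold, with 2022 at an unadjusted p under 0.05 in edgeR (678 expected by chance). STC2 was lower with antimycin than with piericidin, at 35.5 ± 2.71 against 57.5 ± 7.58 CPM (ratio 0.618, −0.70 ± 0.08, adjusted p = 8e-09). MT-RNR2, the large mitochondrial ribosomal RNA (ENSG00000210082, mitochondrial genome, 1671 to 3229), was 1.39-fold higher with antimycin (0.47 ± 0.05, adjusted p = 1.54e-07). The integrated stress response list had 3 of 19 lower with antimycin (14 adjusted over the list alone; median −0.25, adjusted p = 1.12e-13, and 0.0767 with an estimated correlation). The mtDNA-encoded mRNAs had 3 of 13 higher (13 adjusted over the list alone; median 0.30, adjusted p = 3.4e-16, and 0.102 with an estimated correlation), and cytosolic ribosomal proteins 3 of 49 higher (20 adjusted over the list alone; adjusted p = 1.79e-13, and 0.203 with an estimated correlation). TXNIP (−0.47 ± 0.13, adjusted p = 0.0608), ASNS (−0.20 ± 0.09, 0.277), TRIB3 (−0.22 ± 0.08, 0.15), ATF4 (−0.14 ± 0.04, 0.0754) and MT-ND1 (0.27 ± 0.10, 0.177) did not pass. CHAC1 was lower with antimycin (−1.06, adjusted p = 0.0277) but not without antimycin library 4 (0.0843), piericidin library 3 (0.0823) or piericidin library 4 (0.123), nor when only the 2 groups were fitted (0.124). In all 68 genes were higher and 50 lower, while DESeq2 called 253 and 40. This count rested on single libraries: it was 480 without antimycin library 1, 13 without library 3, 30 without library 4, 289 without piericidin library 1, 48 without library 2, 35 without library 3 and 6 without library 4. Without antimycin libraries 3 and 4 it was 15, of which 8 were in the count of 118, and the mtDNA-encoded mRNAs then had 0 members past the threshold in edgeR.

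Piericidin and antimycin were compared with the same vehicle libraries. Both raised 141 genes and both lowered 39, where independent lists of these sizes would share 7.5 and 3.3, and none went opposite ways. The log2 changes correlated across genes, which are not independent replicates, at r = 0.544 with a covariance of 0.0256. Unchanged groups simulated against the same controls gave r = 0.502 and a covariance of 0.01355 (median of 20 sets), which leaves a covariance of 0.0121. The median number of genes called was 0 in either simulated comparison, so the simulation gives no measure for the shared calls. Simulated genes varied independently of each other, so any covariance from differences between libraries that genes share was not subtracted. With the vehicle libraries split, so that each inhibitor had its own pair, 44 or 56 genes were higher in both and 5 or 6 lower in both, depending on the pair, with r = 0.185 or 0.119 and covariances of 0.0137 or 0.0094.

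mitoTEMPO alone for 24 h acted most on RNA from the mitochondrial genome. The ribosomal RNAs rose, MT-RNR1 2.53-fold, from 565 ± 30.3 to 1428 ± 64.5 CPM (1.34 ± 0.07, adjusted p = 6.24e-10), and MT-RNR2 2.26-fold, from 3080 ± 149 to 6950 ± 364 CPM (1.17 ± 0.05, adjusted p = 1.03e-18). MT-ND1, the first mRNA after them on the heavy strand and a complex I subunit (ENSG00000198888, mitochondrial genome, 3307 to 4262), rose 1.65-fold (0.72 ± 0.10). MT-ATP6, an ATP synthase subunit (ENSG00000198899, mitochondrial genome, 8527 to 9207), fell to 0.474 of vehicle, from 1263 ± 140 to 599 ± 97.8 CPM (−1.08 ± 0.10, adjusted p = 3.15e-06), and MT-ATP8, whose annotation overlaps it, to 0.458. MT-ND3 fell to 0.533, MT-CO3 to 0.556 and MT-ND4 to 0.581. Of the 13 mtDNA-encoded mRNAs 1 rose and 9 fell (2 and 10 adjusted over the list alone; median −0.57, adjusted p = 9.63e-36, and 0.0196 with an estimated correlation). The share of counts from the mitochondrial genome averaged 1.77 percent in vehicle and 1.91 percent with mitoTEMPO. Near-identical nuclear copies exist for several of these genes, so their counts are uncertain to that extent, and MT-ND6 lies on the light strand, where reads cannot be told from those of genes opposite it without strand information.

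Outside the mitochondrial genome the changes with mitoTEMPO were smaller. TXNIP fell to 0.626 of vehicle, to 26.2 ± 0.917 CPM (−0.68 ± 0.09, adjusted p = 1.03e-06), ADM2 rose 1.7-fold and CLU, the extracellular chaperone clusterin, 1.66-fold. In the integrated stress response 5 of 19 rose (8 adjusted over the list alone; median 0.26, adjusted p = 1.43e-07, and 0.174 with an estimated correlation), ATF4 by 0.30 ± 0.04 (adjusted p = 3.8e-06). The values of ASNS (0.07 ± 0.12, adjusted p = 0.822), TRIB3 (0.12, 0.504), CHAC1 (0.48 ± 0.30, 0.43), ATF3 (0.40 ± 0.24, 0.375), DDIT3 (0.13 ± 0.15, 0.701) and NQO1 (0.24 ± 0.15, 0.398) did not pass. Amino acid transporters had 4 of 11 higher (4 adjusted over the list alone; adjusted p = 0.000635, and 0.385 with an estimated correlation), SLC1A5 among them at 1.16-fold. NRF2 targets had 2 of 16 higher (6 adjusted over the list alone; adjusted p = 0.00106, and 0.303 with an estimated correlation). Nuclear complex I subunits had 2 of 37 higher (7 adjusted over the list alone; adjusted p = 0.00686, and 0.385 with an estimated correlation). Ribosome biogenesis had 5 of 22 lower (6 adjusted over the list alone; adjusted p = 0.0036, and 0.385 with an estimated correlation), with POLR1B at 0.82. The ER chaperones HSPA5 and HSP90B1 fell to 0.847 and 0.867, with their list not called (2 of 17 higher and 2 lower, adjusted p = 0.124), and HMGCS1 fell to 0.851 with cholesterol synthesis not called (adjusted p = 0.124). MYC fell by 0.14 ± 0.04 on the log2 scale (adjusted p = 0.0388), a call lost without mitoTEMPO library 3 (0.0756) or 4 (0.181) and vehicle library 1 (0.114) or 2 (0.103), 0.181 being the highest of its alternatives.

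With mitoTEMPO 242 genes rose and 297 fell at 24 h (209 and 392 by DESeq2), 16 and 15 of them by more than 1.5-fold. The total of 539 was 216 without mitoTEMPO library 1, 269 without library 3, 265 without vehicle library 1, 350 without library 3 and 257 without library 4, and 1161 when only the 2 groups were fitted.

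**Figure D2:**
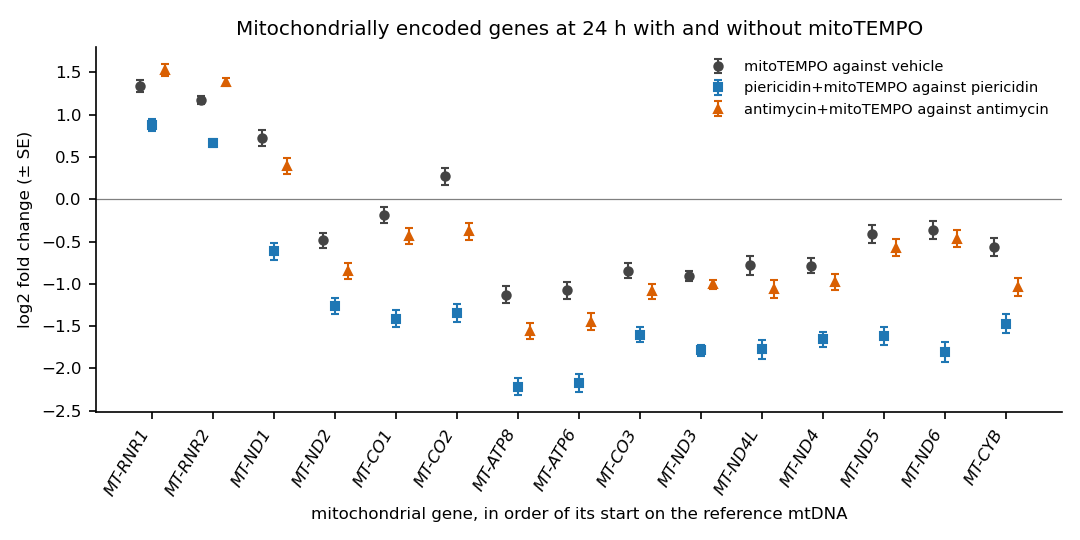
Log2 change ± SE (y axis) of the 15 rRNA and mRNA genes of the mitochondrial genome in map order (x axis) for mitoTEMPO against vehicle, piericidin and mitoTEMPO against piericidin, and antimycin and mitoTEMPO against antimycin, n = 4 per group at 24 h. MT-RNR2 lay at 1.17, 0.67 and 1.38, and MT-ATP6 at −1.08, −2.17 and −1.45.

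mitoTEMPO added to piericidin for 24 h gave the largest count of changed genes of these comparisons, and it raised the stress response further. SLC6A9 rose 2.81-fold over piericidin alone (1.49 ± 0.15), CHAC1 2.25-fold, from 13.8 ± 3.31 to 31.0 ± 5.38 CPM (1.17 ± 0.17), STC2 2-fold (1.00 ± 0.07), SESN2 1.98-fold, ATF3 1.94-fold and ASNS 1.9-fold, to 74.3 ± 8.59 CPM (0.92 ± 0.08, adjusted p = 5.44e-12). ATF4 rose 1.39-fold (0.48 ± 0.04, adjusted p = 1.28e-13) and TRIB3 1.58-fold. All 13 mtDNA-encoded mRNAs fell (13 adjusted over the list alone; median −1.62, adjusted p = 6.76e-188, and 4.78e-07 with an estimated correlation). MT-ATP6 fell to 0.222 of its level with piericidin, from 1296 ± 112 to 287 ± 15.8 CPM (−2.17 ± 0.10), MT-ND3 to 0.29, MT-ND4 to 0.317 and MT-ND1 to 0.652 (−0.62 ± 0.10). MT-RNR1 and MT-RNR2, chosen here after their values were seen, rose by 0.88 ± 0.07 and 0.67 ± 0.05 (adjusted p = 7.39e-08 and 4.36e-12). They fell outside the rule for named genes here, so the alternatives were not run for them in this comparison. The mitochondrial share of counts averaged 1.80 percent with piericidin and 1.02 percent with both compounds.

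The integrated stress response list had 16 of 19 higher with mitoTEMPO added to piericidin (16 adjusted over the list alone; median 0.73, adjusted p = 1.13e-45, and 0.000136 with an estimated correlation), and amino acid transporters 9 of 11 (9 adjusted over the list alone; median 0.32, adjusted p = 7.15e-27, and 0.00215 with an estimated correlation), with SLC38A2 at 1.61-fold and SLC1A4 at 1.44-fold. Cytosolic tRNA synthetases had 11 of 20 higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 1.56e-06, and 0.0989 with an estimated correlation). PHGDH rose 1.5-fold, PSAT1 1.64-fold and MTHFD2 1.49-fold in a serine list with 4 of 12 higher and 2 lower (estimated correlation, adjusted p = 0.133). NRF2 targets had 7 of 16 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 4.73e-05, and 0.0989 with an estimated correlation). These included TXNRD1, thioredoxin reductase, at 1.28-fold, the cystine transporter gene SLC7A11 at 1.9-fold, and FTH1, ferritin heavy chain, at 1.38-fold. SLC7A11 is also a member of the amino acid transporter list, so its rise is not particular to NRF2 targets. NQO1 rose by 0.52 (adjusted p = 0.00604), a call lost without piericidin library 2 (0.0718).

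In the same comparison ribosome biogenesis had 13 of 22 lower (20 adjusted over the list alone; median −0.17, adjusted p = 9.04e-14, and 0.0135 with an estimated correlation), with LYAR at 0.794 and NOP56 at 0.821. Nucleotide synthesis had 8 of 16 lower (8 adjusted over the list alone; adjusted p = 1.77e-05, and 0.0387 with an estimated correlation), with CAD, which starts pyrimidine synthesis, at 0.824 and DHODH at 0.806. Of 51 mitochondrial ribosome genes 10 were lower (16 adjusted over the list alone; adjusted p = 7.94e-06, and 0.0989 with an estimated correlation). Of 22 TCA cycle genes 5 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00515, and 0.19 with an estimated correlation), with SDHA at 0.839 and DLD at 0.844. In the ER list 8 of 17 fell and 4 rose (9 and 4 adjusted over the list alone; median −0.17, adjusted p = 0.00512, and 0.0989 with an estimated correlation). HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) fell to 0.733, from 433 ± 18.6 to 317 ± 13.5 CPM (−0.45 ± 0.04, adjusted p = 1.59e-12), while EDEM1 rose 1.23-fold. FASN, fatty acid synthase, fell to 0.763 (−0.39 ± 0.04), in a list whose call did not hold with an estimated correlation (1 of 10 higher and 3 lower, adjusted p = 0.0409, and 0.19 with the estimate), with only the 2 groups fitted (0.0672), or without piericidin library 1 (0.0723), piericidin library 2 (0.0974) or combination library 4 (0.11).

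In all 731 genes rose and 788 fell when mitoTEMPO was added to piericidin, 96 and 56 by more than 1.5-fold, and no left-out library moved the count of 1519 by more than 1.5 times. TXNIP rose by 0.35 (adjusted p = 0.0408), but not with DESeq2 (0.0695), without the filter (0.067), with only these groups fitted (0.0671), or without piericidin library 1 (0.0608), 2 (0.17) or 4 (0.093) or combination library 3 (0.0829) or 4 (0.309). MYC (−0.08 ± 0.04, adjusted p = 0.222) and DDIT3 (0.20 ± 0.14, 0.404) did not pass. List median, mean and test differed in sign, with no call, for hypoxia-inducible factor targets (5 of 15 higher; median −0.01, mean 0.04, test up, adjusted p = 0.263) and NOTCH targets (3 of 8 lower; median −0.04, mean 0.02, test down, 0.385).

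mitoTEMPO added to antimycin for 24 h again moved mitochondrial RNA. MT-RNR1 rose 2.89-fold (1.53 ± 0.07) and MT-RNR2 2.61-fold, from 3469 ± 232 to 9050 ± 713 CPM (1.38 ± 0.05, adjusted p = 5.25e-21), while MT-ATP6 fell to 0.367, from 1573 ± 67.2 to 577 ± 35.7 CPM (−1.45 ± 0.10). MT-ATP8 fell to 0.339, MT-CO3 to 0.47 and MT-CYB to 0.488. Of the 13 mtDNA-encoded mRNAs 11 fell and 1 rose (12 and 1 adjusted over the list alone; median −0.98, adjusted p = 6.89e-98, and 5.69e-05 with an estimated correlation). The one that rose was MT-ND1 (0.39, adjusted p = 0.0463), whose call was lost without antimycin library 2 (0.168), 3 (0.0551) or 4 (0.102), without combination library 1 (0.102), 2 (0.0685), 3 (0.112) or 4 (0.101), without antimycin libraries 3 and 4 together (0.107) and without the filter on low counts (0.087). In the integrated stress response 9 of 19 rose (15 adjusted over the list alone; median 0.34, adjusted p = 9.69e-18, and 0.0152 with an estimated correlation), with STC2 at 1.42-fold, ATF5 at 1.41-fold and ATF4 at 1.16-fold (0.22 ± 0.04). Amino acid transporters had 6 of 11 higher (9 adjusted over the list alone; adjusted p = 1.56e-11, and 0.0424 with an estimated correlation), with SLC38A2 at 1.23-fold. NRF2 targets had 5 of 16 higher (9 adjusted over the list alone; adjusted p = 4.64e-10, and 0.0233 with an estimated correlation), with TXNRD1 at 1.2-fold, and HSPA5 fell to 0.847 (−0.24 ± 0.04, adjusted p = 0.000147). ASNS rose by 0.35 (adjusted p = 0.033), but not without antimycin library 2 (0.188) or combination library 3 (0.102) or 4 (0.131), nor with only these groups fitted (0.0565). TRIB3 rose by 0.34 (0.0142), but not without antimycin library 1 (0.0624) or 2 (0.103) or combination library 3 (0.069). CHAC1 (0.68 ± 0.23, adjusted p = 0.173), ATF3 (0.24 ± 0.20, 0.637), NQO1 (0.36, 0.188), TXNIP (−0.12 ± 0.14, 0.772), MYC (−0.09 ± 0.04, 0.334) and DDIT3 (−0.04, 0.932) did not pass. In all 123 genes rose and 77 fell. The count of 200 was 94 without antimycin library 1, 73 without library 2, 390 without library 3, 84 without combination library 3, and 81 when only the 2 groups were fitted. Without antimycin libraries 3 and 4 it was 1085 (464 higher, 621 lower, 180 of them in the count of 200), the integrated stress response then had 15 higher and NRF2 targets 9 higher.

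Whether mitoTEMPO acted differently once an inhibitor was present was tested as an interaction, the log2 effect of mitoTEMPO with the inhibitor minus its effect in vehicle. For piericidin the interaction was positive for ASNS (0.86 ± 0.15, adjusted p = 0.000228), STC2 (0.75 ± 0.12), TRIB3 (0.55 ± 0.11) and MTHFD2 (0.57 ± 0.09), whose levels rose more with both compounds than the single effects added up to. It was also positive for TXNIP (1.03 ± 0.15, adjusted p = 7.76e-06). It was negative for mtDNA-encoded mRNAs, with all 13 lower (13 adjusted over the list alone; median −1.09, adjusted p = 3.2e-67, and 0.000668 with an estimated correlation), including MT-CO2 (−1.62 ± 0.15, adjusted p = 4.55e-06) and MT-ND1 (−1.34 ± 0.14). Among integrated stress response genes 7 of 19 were higher (9 adjusted over the list alone; median 0.36, adjusted p = 3.77e-11, and 0.135 with an estimated correlation), amino acid transporters 6 of 11 (8 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation) and tRNA synthetases 8 of 20 with 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). Ribosome biogenesis had 7 of 22 lower (9 adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). ATF4 (0.18 ± 0.06, adjusted p = 0.0712), CHAC1 (0.70 ± 0.35, 0.27), ATF3 (0.55 ± 0.30, 0.288), DDIT3 (0.07, 0.886), NQO1 (0.28 ± 0.20, 0.467) and MYC (0.06, 0.62) did not pass. HSPA5 had −0.21 (adjusted p = 0.0274), a call lost without mitoTEMPO library 3 (0.0799) or 4 (0.0511), piericidin library 1 (0.0725) or 2 (0.062), combination library 3 (0.065) or 4 (0.0546), or vehicle library 1 (0.0713) or 2 (0.0877). In all 274 genes were higher and 383 lower. The count of 657 was 315 without mitoTEMPO library 1, 367 and 368 without piericidin libraries 2 and 4, 299 without combination library 4, and 398, 413 and 330 without vehicle libraries 1, 3 and 4, and 996 when only these groups were fitted.

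For antimycin the same interaction called 0 genes with edgeR and 0 with DESeq2, with 1026 at an unadjusted p under 0.05 and a smallest adjusted p of 0.449. ASNS had 0.28 ± 0.15 (adjusted p = 0.702), TXNIP 0.56 ± 0.17 (0.546), MT-CO2 −0.65 ± 0.14 (0.546) and HSPA5 0.00 ± 0.06. The mtDNA-encoded mRNAs had 6 lower adjusted over the list alone (median −0.28, adjusted p = 5.81e-10, and 0.844 with an estimated correlation). Without antimycin libraries 3 and 4 the count was 226, 31 higher and 195 lower. The direct test of piericidin's interaction minus antimycin's called 6 genes higher and 22 lower. GRB10, a growth factor receptor adaptor (0.51 ± 0.09, adjusted p = 0.000457), and SLC38A2 (0.38 ± 0.07, 0.00284) were higher. FASN (−0.37 ± 0.06, 0.000457), MT-ND3 (−0.78 ± 0.09, 1.62e-06), MT-ND6 (−1.34 ± 0.16) and MT-ND1 (−1.01 ± 0.14) were lower. The mtDNA-encoded mRNAs had 8 of 13 lower (13 adjusted over the list alone; median −0.73, adjusted p = 1.15e-60, and 0.00122 with an estimated correlation). The integrated stress response had 3 of 19 higher (10 adjusted over the list alone; median 0.26, adjusted p = 1.46e-14, and 0.035 with an estimated correlation). The count of 28 was 18 without antimycin-mitoTEMPO library 1, 16 without library 3 and 121 without library 4, 17 without piericidin library 2, and 63, 17 and 16 without piericidin-mitoTEMPO libraries 1, 3 and 4. DESeq2 called 71. Without antimycin libraries 3 and 4 it was 159, with 24 of the 28 among them, and the integrated stress response then had 1 higher and an adjusted p of 0.257 with an estimated correlation.

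At 1 h the question was which transcripts moved first. TXNIP fell with both inhibitors, from 72.4 ± 7.17 CPM in vehicle to 32.9 ± 6.29 with piericidin (−1.14 ± 0.15, adjusted p = 0.00259) and to 0.47 of vehicle with antimycin (−1.09 ± 0.15, adjusted p = 0.00551). It was the single gene past the threshold for each, with 1062 and 488 genes at an unadjusted p under 0.05. DESeq2 called 38 and 1. Both calls were lost with replicates 1 and 2 only (−1.01, adjusted p = 0.271, and −1.08, 0.584, with n = 2 per group) and kept with replicates 3 and 4 only. The 1 h libraries parted into replicates 1 and 2 against replicates 3 and 4 in every treatment, and this difference, not a treatment, moved the stress genes most. All 19 integrated stress response genes were higher in replicates 1 and 2 (median 1.17, adjusted p = 5.76e-09 with an estimated correlation), ASNS by 1.63 ± 0.03 and CHAC1 by 1.34 ± 0.12. All 22 ribosome biogenesis genes were lower there (median −0.59). This comparison took its split from the data and treated all 24 libraries at 1 h as independent. Its p-value and SEs therefore measure the scatter between libraries, not how far the difference would repeat. With the replicate number as a block, which also takes up the difference between these pairs of replicates, the calls below were made.

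**Figure D3:**
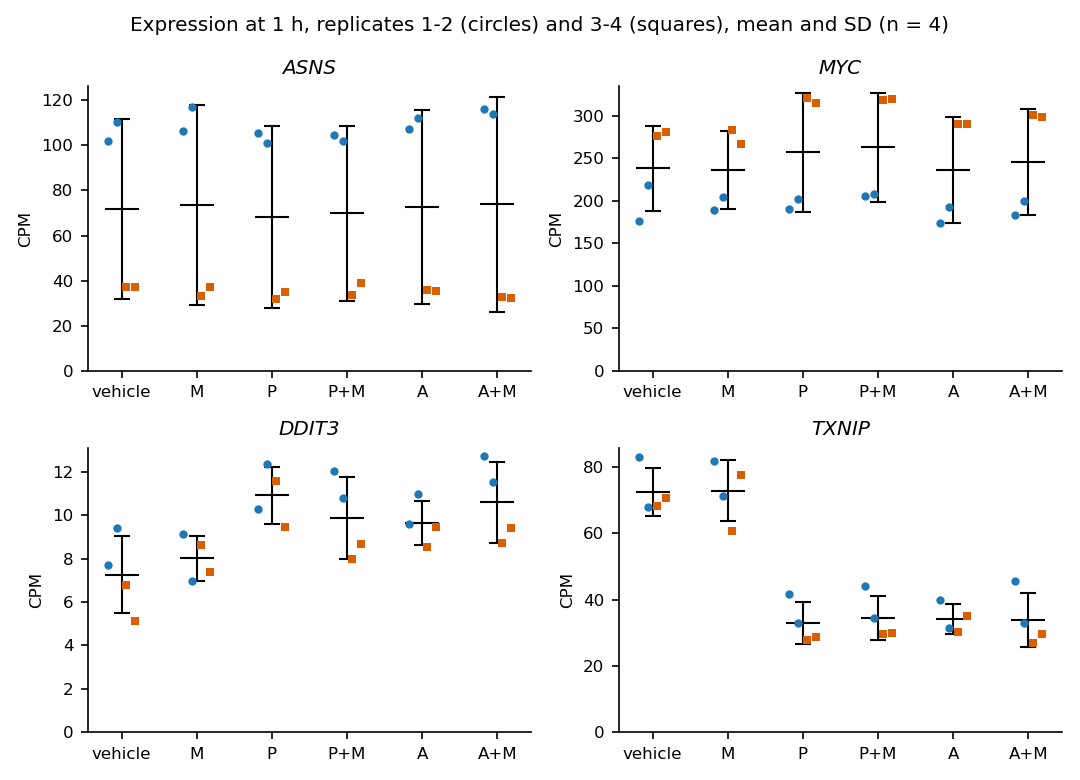
CPM of ASNS, MYC, DDIT3 and TXNIP in each 1 h library (circles, replicates 1 and 2; squares, replicates 3 and 4) with mean and SD of the 4 libraries per treatment (x axis: treatment; y axis: CPM). TXNIP averaged 72.4 CPM in vehicle and 32.9 with piericidin, while ASNS differed by 1.63 on the log2 scale between the pairs of replicates.

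In the blocked fit, 1 h of piericidin lowered TXNIP to 0.453 of vehicle (−1.14 ± 0.07, adjusted p = 1.72e-31), KLF10, a transcription factor induced by TGF-beta (ENSG00000155090, chromosome 8, 102648779 to 102655902), to 0.561 (−0.83 ± 0.08), and SLC30A1, the zinc exporter of the plasma membrane, to 0.742 (−0.43 ± 0.04, adjusted p = 1.4e-13). Of the immediate early genes, which include KLF10, some rose: JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327) 1.34-fold, from 63.2 ± 4.8 to 84.6 ± 2.9 CPM (0.42 ± 0.06, adjusted p = 7.99e-09), EGR1 1.39-fold and FOSB 1.31-fold. Their list had 5 of 25 higher and 3 lower (7 and 5 adjusted over the list alone) with no call (adjusted p = 0.483, median −0.04, mean 0.00, test up). Of the integrated stress response genes 4 of 19 were higher (6 adjusted over the list alone; median 0.12, adjusted p = 3.16e-05, and 0.0102 with an estimated correlation), with CHAC1 at 1.53-fold (0.61 ± 0.12), SESN2 at 1.2-fold and ATF4 at 1.14-fold (0.19 ± 0.03, adjusted p = 3.91e-07). DDIT3 rose by 0.59 ± 0.14 (adjusted p = 0.00457), a call lost without piericidin library 3 (0.0605). ASNS (−0.08 ± 0.06, adjusted p = 0.512), ATF3 (0.13 ± 0.11, 0.583), TRIB3 (0.06, 0.604), HSPA5 (0.07, 0.145), MYC (0.10 ± 0.04, 0.0874), NQO1 (0.17 ± 0.18, 0.691) and MT-ND1 (−0.04 ± 0.06, 0.778) did not pass. Of 49 cytosolic ribosomal proteins, many of which have near-identical pseudogenes, 22 rose and none fell (24 adjusted over the list alone; median 0.08, adjusted p = 8.91e-19, and 0.162 with an estimated correlation), with RPL8 at 1.13-fold and RPS15 higher by 0.20 ± 0.03. Glycolysis had 6 of 19 higher (8 and 1 lower adjusted over the list alone; adjusted p = 0.000568, and 0.23 with an estimated correlation), with ENO1 at 1.09-fold. Complex I had 4 of 37 higher (4 adjusted over the list alone; adjusted p = 0.000521, and 0.23 with an estimated correlation), with NDUFA1 at 1.27-fold. Antioxidant enzymes had 3 of 15 higher (4 adjusted over the list alone; adjusted p = 0.00345, and 0.155 with an estimated correlation), PRDX5 and GPX4 at 1.17-fold, a list call lost without vehicle library 2 (0.0715). In all 365 genes rose and 302 fell. The count of 667 was 317 and 405 without piericidin libraries 3 and 4, 358 and 389 without vehicle libraries 2 and 3, 397 with DESeq2 and 1213 with only these groups fitted. Fitted alone, replicates 1 and 2 called 1 gene and replicates 3 and 4 called 360, of which 279 were in the blocked count. The mtDNA-encoded mRNAs had a median of 0.09 in the first pair and −0.15 in the second (adjusted p = 0.666 and 0.134 with an estimated correlation).

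Antimycin for 1 h, in the blocked fit, lowered TXNIP to 0.47 (−1.09 ± 0.07, adjusted p = 1.35e-29), KLF10 to 0.597 (−0.75 ± 0.08) and SLC30A1 to 0.824 (−0.28 ± 0.04), and raised ATF4 1.11-fold (0.15 ± 0.03, adjusted p = 0.000491) and RSRC2 1.16-fold. The integrated stress response had 3 of 19 higher (4 adjusted over the list alone; median 0.09, adjusted p = 0.000223, and 0.0292 with an estimated correlation), with CHAC1 at 0.60 (adjusted p = 0.00549), a call lost without antimycin library 2 (0.0508) or vehicle library 2 (0.132). Immediate early genes had 2 of 25 higher and 3 lower (2 and 7 adjusted over the list alone; median −0.11, adjusted p = 0.00222, and 0.3 with an estimated correlation). ASNS (0.01 ± 0.06, adjusted p = 0.982), DDIT3 (0.41 ± 0.15, 0.297), ATF3 (0.16 ± 0.11, 0.705), HSPA5 (0.05, 0.621), MYC (−0.02, 0.943) and MT-ND1 (0.00 ± 0.06, 0.996) did not pass. The blocked count was 18 higher and 35 lower. It was 35 and 33 without antimycin libraries 1 and 3, 23 and 34 without vehicle libraries 2 and 3, 28 with DESeq2, and 2 and 7 when replicates 1 and 2 or replicates 3 and 4 were fitted alone.

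Between the inhibitors at 1 h, the blocked fit called 126 genes higher and 341 lower with antimycin than with piericidin, where the fit without the block called 0 with edgeR (883 at an unadjusted p under 0.05) and 20 with DESeq2. Higher with antimycin was ATAD5, a PCNA unloading factor, by 0.32 ± 0.05 on the log2 scale (adjusted p = 1.38e-05). Of 49 ribosomal proteins 13 were lower (16 adjusted over the list alone; adjusted p = 1.94e-09, and 0.406 with an estimated correlation), with RPS15 at −0.27 ± 0.03 and RPL13 at −0.18 ± 0.03, and 6 of 19 glycolysis genes were lower (8 adjusted over the list alone; adjusted p = 0.406 with an estimated correlation), with ALDOA at 0.921. FARSA, GPX4 and PRDX2 were lower at 0.841, 0.849 and 0.862. The count of 467 was 291 and 186 without antimycin libraries 1 and 3 and 149 and 277 without piericidin libraries 3 and 4. Replicates 1 and 2 alone gave 1 call and replicates 3 and 4 alone 391.

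mitoTEMPO had little effect that could be resolved at 1 h. Without the block edgeR called 0 genes for mitoTEMPO against vehicle (595 at an unadjusted p under 0.05), 0 for its addition to piericidin (300), 0 for its addition to antimycin (334), 0 for the piericidin interaction (621), 0 for the antimycin interaction (633) and 0 for their difference (242). DESeq2 called 0 for each of these. With the block mitoTEMPO had 25 genes higher and 16 lower than vehicle (32 and 13 by DESeq2). Among them RPS15, a small-subunit ribosomal protein, was lower (−0.20, adjusted p = 0.00173), a call lost without mitoTEMPO library 4 (0.105) or vehicle library 1 (0.081). TXNIP stood at 0.01 ± 0.06 (adjusted p = 0.979). The mtDNA-encoded mRNAs had 3 of 13 lower adjusted over the list alone with mitoTEMPO (median −0.08, adjusted p = 4.52e-05, and 0.549 with an estimated correlation), 3 when it was added to piericidin (median −0.10, adjusted p = 2.23e-09, and 0.546) and 2 when it was added to antimycin (median −0.09, adjusted p = 1.38e-06, and 0.428). The blocked count for mitoTEMPO was 8, 79, 14 and 1 without its libraries 1 to 4 and 2, 9, 5 and 7 without vehicle libraries 1 to 4, and 85 with replicates 3 and 4 alone, where replicates 1 and 2 alone gave 0 with edgeR (868 at an unadjusted p under 0.05). Blocked, the additions to piericidin and antimycin called 0 genes with edgeR (832 and 922 at an unadjusted p under 0.05) and 4 and 0 with DESeq2. The blocked interactions called 18 genes for piericidin, RFX7 among them (−0.32 ± 0.06, adjusted p = 0.00156), 51 for antimycin, with RPS15 higher (0.30 ± 0.05, adjusted p = 0.000765), and 0 for their difference (602 at an unadjusted p under 0.05; 0 with DESeq2). Fitted alone, replicates 1 and 2 called 0 genes with edgeR for the interactions of piericidin (1172 at an unadjusted p under 0.05) and antimycin (717), and replicates 3 and 4 called 0 (1245) and 258. For piericidin that count was 82 and 1 without mitoTEMPO libraries 2 and 4, 42 without piericidin library 2, 55, 7, 39 and 33 without piericidin-mitoTEMPO libraries 1 to 4, and 7 and 34 without vehicle libraries 1 and 3. For antimycin it was 28 and 2 without antimycin libraries 2 and 3, 202, 195, 1 and 10 without antimycin-mitoTEMPO libraries 1 to 4, 137, 9 and 2 without mitoTEMPO libraries 2 to 4, and 3, 32 and 18 without vehicle libraries 1, 3 and 4. The blocked counts of 0 became 1 or 2 without single libraries: for the addition to piericidin, piericidin or combination library 1; for the addition to antimycin, antimycin library 1 or 2 or combination library 1; for the difference, antimycin library 1 or 2, antimycin-mitoTEMPO library 1, piericidin library 4 or piericidin-mitoTEMPO library 3 or 4.

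The time courses were compared as the effect at 24 h minus the effect at 1 h. The piericidin effect grew for cholesterol synthesis, with HMGCS1 (0.58 ± 0.09, adjusted p = 0.000216) and MSMO1 (0.49 ± 0.08) past the threshold and 3 of 23 list members higher (11 adjusted over the list alone; median 0.21, adjusted p = 9.34e-17, and 4.77e-06 with an estimated correlation). The antimycin effect did so too, for HMGCS1 (0.69 ± 0.09), MSMO1, FDFT1 and SREBF2, with 4 of 23 higher (16 adjusted over the list alone; median 0.28, adjusted p = 5.92e-34, and 1.45e-09 with an estimated correlation), and MT-CO2 rose by 0.76 ± 0.13 more at 24 h. Its lists of mtDNA-encoded mRNAs (1 of 13 higher, 10 adjusted over the list alone; median 0.32, adjusted p = 4.66e-18, and 0.0369 with an estimated correlation) and fatty acid synthesis (1 of 10 higher, 3 adjusted over the list alone; adjusted p = 0.00012, and 0.0369) were also called higher. So were NRF2 targets (0 of 16 past the threshold in edgeR, 4 adjusted over the list alone; adjusted p = 4.77e-06, and 0.0483) and the BCL2 family (0 of 14 in edgeR, also 0 adjusted over the list alone; adjusted p = 0.0109, and 0.0483). The last call was lost without vehicle 1 h library 1 (0.0512) or antimycin 24 h libraries 3 and 4 (0.119). For piericidin camera also called lists lower. The mitochondrial ribosome had 0 of 51 members past the threshold (median −0.185, adjusted p = 1.99e-12, and 0.146 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 49 (median −0.103, adjusted p = 1.92e-11, and 0.338), and complexes IV and V 1 of 25 (adjusted p = 3.54e-07, and 0.146). These did not hold with the estimate, and their other alternatives are not given. The integrated stress response list was called higher at 24 h for piericidin (18 of 19 positive, median 0.70, adjusted p = 7.36e-06). It had 0 members past the threshold in edgeR, and no call with an estimated correlation (adjusted p = 0.436). For antimycin 18 of 19 members were also positive (median 0.41, camera adjusted p = 0.00745, and 0.801 with the estimate), with 0 past the threshold in edgeR. Other alternatives for this antimycin list are not given. These main fits had no term for the difference between replicates 1 and 2 and replicates 3 and 4 at 1 h. That difference was large in these genes (median 1.17) and limits what the fits can call. For mitoTEMPO MT-RNR2 rose by 1.17 ± 0.08 more at 24 h (adjusted p = 1.97e-14) and MT-ATP6 fell by 0.98 ± 0.11 more, with 1 of 13 mtDNA-encoded mRNAs higher and 7 lower (1 and 10 adjusted over the list alone; median −0.51, adjusted p = 3.36e-20, and 0.0624 with an estimated correlation). The counts were 9 for piericidin, 8 for antimycin and 142 for mitoTEMPO, the last with 30 higher and 112 lower (79 and 173 by DESeq2). With the replicate block they were 18, 16 and 286, the last with 77 higher and 209 lower. This block gave same-numbered libraries of both times a single shared term, though at 24 h they share only a number. For piericidin the count was 4, 4, 5 and 5 without piericidin 1 h libraries 1 and 3, vehicle 1 h library 2 and vehicle 24 h library 1. For mitoTEMPO it was 59, 39 and 21 without mitoTEMPO 1 h libraries 1, 3 and 4. It was 31, 44, 31 and 74 without its 24 h libraries 1 to 4. It was 33, 46, 58 and 88 without vehicle 1 h libraries 1 to 4. Further counts were 18, 88 and 64 without vehicle 24 h libraries 1, 3 and 4, and 25 when only these groups were fitted.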

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

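Of the tests in this part, those of library scaling, of distance from the promoters, of antimycin libraries 3 and 4, of the error of the antimycin contrast, and of a response that differs between the inhibitors were chosen after the results were seen.

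Single libraries stood far from the other 3 of their group in 5 of 180 group values tested, where chance gives about 1 in 20 groups, or 9.0. The gap to the nearest library, as a share of the group's range, was 0.874 for genes with at least 10 counts in antimycin and mitoTEMPO library 4 at 24 h (12673 genes against 12819 to 12840). It was 0.859 for TXNIP in library 3 of the same group (9.41 against 7.46 to 7.73 CPM) and 0.832 for CHAC1 in mitoTEMPO library 3 at 24 h (7.29 against 4.37 to 4.86 CPM). For HSPA5 in piericidin and mitoTEMPO library 2 at 24 h it was 0.841 (337.29 against 308.43 to 313.02 CPM), and for ASNS in vehicle library 2 at 24 h it was 0.836 (14.68 against 16.23 to 16.53 CPM).

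Differences between effects stood out as tested contrasts with genes past the threshold. The effect of mitoTEMPO differed between piericidin and vehicle at 24 h in 657 genes, and this interaction differed from that of antimycin in 28. Effects at 24 h differed from those at 1 h in 9 genes for piericidin, 8 for antimycin and 142 for mitoTEMPO. With the replicate block, the interactions at 1 h had 18 genes for piericidin and 51 for antimycin.

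With mitoTEMPO at 24 h the mitochondrial ribosomal RNAs rose and most mtDNA-encoded mRNAs fell. Library scaling cannot make this, because the log2 ratio of MT-RNR2 to MT-ATP6 within libraries rose by 2.26 (SE 0.147) over vehicle. Reads of MT-ATP6 did not move to its nuclear copy MTATP6P1, which lost CPM along with it (a gain of −15.2 percent of its loss, from 195 to 94.1 CPM). Nuclear copies of the other genes were not examined, so moves of reads to them are not excluded. More RNA without poly(A) tails in these libraries cannot be told apart, since 1 of 24 such nuclear RNAs was measured (median log2 0.306). A lower output of transcription with distance from the heavy-strand promoters stays open as a hypothesis: change fell with position over 14 genes (Spearman rho −0.59, permutation p = 0.0309, Benjamini-Hochberg adjusted p = 0.0309), but over the 12 mRNAs alone rho was −0.34 (permutation p = 0.278), so it cannot be told apart from a difference between ribosomal RNAs and mRNAs.

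At 24 h 657 genes depended on both piericidin and mitoTEMPO, and 0 on antimycin and mitoTEMPO (edgeR; 1026 at an unadjusted p under 0.05; 0 with DESeq2). From the spread within each interaction's own groups, the median standard error was 1.03 times as large for antimycin as for piericidin. Both interactions share the vehicle and mitoTEMPO groups, which pulls this ratio towards 1. In the groups not shared, the median SD of log2 CPM was 0.121 with antimycin and 0.116 with antimycin and mitoTEMPO. It was 0.108 with piericidin and 0.117 with piericidin and mitoTEMPO, so a somewhat larger error for antimycin is not excluded. The ratio in the fit (1.009) is near 1 by construction, since the fit pools the spread over groups. The spread within the antimycin group could account for part of the difference in counts. Libraries 1 and 2 differed more from 3 and 4 there (chi-square per degree of freedom 3.06 to 4.39) than with piericidin (1.87 to 2.37), though piericidin and mitoTEMPO reached 3.29. Leaving out any single library gave 0 calls for the antimycin interaction with edgeR. Without antimycin libraries 3 and 4, 226 genes were called, 37 of them in both interactions. No other pair of libraries was left out for comparison, so this rise cannot be credited to those libraries. A response that differs between the inhibitors is also open as a hypothesis, since without those libraries the interactions still differed for the mtDNA-encoded mRNAs (median −0.72, camera adjusted p = 5.12e-34, and 0.0334 with an estimated correlation). Both may hold.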

How the results depend on the processing

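Of the tests in this part, the fits of replicates 1 and 2 or 3 and 4 only, the alternatives on the blocked 1 h fits and the fits without antimycin libraries 3 and 4 were chosen after the results were seen. In the settings below P is piericidin, A antimycin, M mitoTEMPO and × an interaction, and the cause was not tested for changed results, except that leaving out libraries leaves fewer samples. No named gene reversed. RLE factors moved no count by over 1.5 times and ended 2 of 451 gene calls and 0 of 167 list calls, DESeq2 ended 7 of 414 gene calls, and an estimated correlation ended 126 of 167 list calls. On the blocked 1 h fits RLE ended 2 of 166 gene calls and 1 of 45 list calls, DESeq2 39 of 132 gene calls, and an estimated correlation 43 of 45 list calls. Fits with only the groups compared ended 63 of 450 gene calls without the block and 1 of 166 with it, and no filter on low counts 46 of 451 and 34 of 166. Leaving out 1 library ended 887 of 4448 gene calls checked without the block and 621 of 1560 with it, and 179 of 1760 and 55 of 408 list calls. After the filter on low counts 13555 genes were tested at 24 h and 14140 at 1 h.

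With a replicate block the 1 h counts were A × M 51, A against P 467, A 53, M 41, P × M 18 and P 667. At 24 h, where same-numbered libraries share only a number (correlations above 0.1 throughout in 0 of 15 pairs of groups, median 0.11, 12 of 24 libraries closest to their own number), the block gave A against P 289, A with M against A 339 and the difference of interactions 79. Time differences under it were A 16, M 286 and P 18, and it moved no other count by over 1.5 times. Replicates 1 and 2 only gave A against P 1, A 2 and P with M against P 3. Replicates 3 and 4 only gave A × M 258, A against P 391, A 7, A with M against A 28, M 85, the difference 8, P 360 and P with M against P 2.

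No filter on low counts gave A × M at 24 h 1, A over time 13, M over time 31, A against P 3 at 1 h and 188 at 24 h, the difference 5 at 1 h and 52 at 24 h, and at 1 h A 8, A with M against A 1, P × M 3, P 10 and P with M against P 3. On blocked fits it gave A with M against A 2, M 24, P × M 31, the difference 1 and P with M against P 2. DESeq2 gave A against P 20 at 1 h and 293 at 24 h, M over time 252, the difference 71 at 24 h, P 38 at 1 h, and blocked A 28, P 397 and P with M against P 4. Fits with only the groups compared gave at 24 h A against P 22, A with M against A 81, M 1161, P × M 996 and P 1612, over time M 25 and P 4, and blocked at 1 h A 105, A with M against A 10, M 254, P × M 202 and P 1213.

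Without antimycin 24 h libraries 3 and 4 counts were A × M 226, A against P 15, A 143, A with M against A 1085 and the difference 159, and 57 of 140 gene calls ended. Lists reversed there were ribosomal proteins in A over time (adjusted p = 0.21), antioxidant enzymes in A (0.863) and the TCA cycle in A with M against A (0.899), all by camera.

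Leaving out 1 library gave ranges at 24 h of P 637 to 1227, A 167 to 343, M 216 to 495, P with M against P 1016 to 1508, A with M against A 73 to 390, A against P 6 to 480, P × M 299 to 862, A × M 0 to 0 (edgeR, 1026 at an unadjusted p under 0.05 with all libraries, 0 with DESeq2) and the difference 16 to 121. Over time they were P 4 to 11, A 8 to 11 and M 18 to 138. At 1 h they were P and A 1 to 1 and others 0 to 0. Blocked at 1 h they were P 317 to 576, A 23 to 47, M 1 to 79, A against P 149 to 435, P × M 1 to 82, A × M 1 to 202, P with M against P 0 to 1, A with M against A 0 to 1 and the difference 0 to 2.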

Other observations

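Of the tests in this part, that of library depth was chosen after the result was seen.

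Zinc-binding and zinc-export genes moved with mitoTEMPO at 24 h. Added to piericidin it raised 3 of 4 measured members (3 adjusted over the list alone; median 0.44, adjusted p = 5.93e-05, and 0.0046 with an estimated correlation): SLC30A1, the zinc exporter, at 1.36-fold (0.44 ± 0.06, n = 4), and the metallothioneins MT2A at 1.36-fold (0.44 ± 0.09) and MT1F at 1.88-fold (0.91 ± 0.22). Added to antimycin it raised 2 (3 adjusted over the list alone; adjusted p = 3.08e-06, and 0.00159 with an estimated correlation), SLC30A1 at 1.27-fold and MT2A at 1.37-fold. MT2A rose 1.38-fold with mitoTEMPO alone. Metallothioneins are near-identical paralogs, so their counts are uncertain.

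HRK, a BH3-only gene that promotes apoptosis, rose 2.33-fold with piericidin at 24 h (1.22 ± 0.22), in a BCL2 family list with 4 of 14 higher (4 adjusted over the list alone; adjusted p = 0.00339, and 0.0198 with an estimated correlation). With mitoTEMPO added to piericidin, PMAIP1, which encodes NOXA, rose 1.3-fold and GABARAPL1, an autophagosome protein, 1.6-fold (0.68 ± 0.13). Their lists there had 3 of 14 higher with no call (BCL2 family, adjusted p = 0.0631) and 3 of 21 higher (autophagy, adjusted p = 0.0401, and 0.0989 with an estimated correlation). The latter call was lost without piericidin library 1 (0.0511) or 2 (0.0741) or combination library 1 (0.0554) or 3 (0.0735) and with only these groups fitted (0.0597). The autophagy list had 3 of 21 higher when mitoTEMPO was added to antimycin (4 adjusted over the list alone; adjusted p = 0.00533, and 0.0233 with an estimated correlation).

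At 1 h replicates 1 and 2 parted from 3 and 4 in every group, with 3916 genes higher and 3635 lower in the first pair. These counts treat the libraries as independent and use a split found in the same data. Depth is excluded (ratio of mean totals 0.983), as is a trend with GC content and length (100.8 percent of the stress list median was left after its removal). RNA from the other cells looked up did not show such a difference. The B cell marker list differed by 0.369 on the log2 scale, and the myeloid, epithelial or fibroblast and erythroid lists averaged at most 0.742 CPM. RNA from further cell types or lines was not examined. No biological explanation was tested, since the labels give no difference between these replicates, and a difference in culture or handling stays open, untested.

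Counts were compared with other splits of the same libraries. At 24 h no other split called as many genes for piericidin (1044 genes, highest other split 4; 1 of 35 splits as large). The same held for antimycin (296, 36; 1), mitoTEMPO (539, 0; 1) and piericidin with mitoTEMPO (1519, 39; 1). It did not hold for antimycin with mitoTEMPO (200, 445; 2) or antimycin against piericidin (118, 151; 2). The real split is counted, so 1 of 35 is the lowest share possible, and it was not adjusted over comparisons. A chance labelling of libraries is thus unlikely for each count that no other split reached. A difference between cultures is not excluded, since the labels do not say that replicates were separate cultures. For interactions 50 splits were drawn, which gave piericidin at 24 h (657, 222; 1) and the difference (28, 406; 4). These splits mix libraries with and without mitoTEMPO and so also remove the effect of mitoTEMPO itself. They do not test the interaction alone, and chance is not excluded for it by them. Splits over time mix treated and vehicle libraries at each time, with the same limit for a change over time. They gave mitoTEMPO (142, 15; 1) and antimycin (8, 14; 4). For piericidin over time 2 of 50 splits were as large (9, 20; 2), which is few, but the other split had more genes than the treatments, so the count of 9 carries little weight. At 1 h without the block chance cannot be excluded for piericidin (1, 383; 2 of 35) or antimycin (1, 1; 2). Where the count is 0 every split is as large by definition, so the comparison says nothing about chance. This holds for the antimycin interaction at 24 h (0, 172; 50) and, at 1 h without the block, for mitoTEMPO (0, 1; 35), its addition to piericidin (0, 1736; 35) or antimycin (0, 1417; 35), antimycin against piericidin (0, 0; 35) and the interactions and their difference (0, 0; 50 each). With the block it holds for the additions to piericidin (0, 1; 8) and antimycin (0, 0; 8) and the difference of interactions (0, 5; 25). The splits with 383, 1736 and 1417 genes at 1 h, and with 36, 445 and 151 at 24 h, set replicates 1 and 2 against 3 and 4 and point to a structure of the samples; blocked counts for the last 2 comparisons were 339 and 289. With the block 8 splits are too few to tell for piericidin (667, highest other 2; 1), antimycin (53, 0; 1), mitoTEMPO (41, 0; 1) and antimycin against piericidin (467, 25; 1). The blocked interactions had 25 splits for piericidin (18, 4; 1) and antimycin (51, 1; 1). These splits also remove the effect of mitoTEMPO itself, so chance is not excluded for the interactions by them. Neither pair of replicates fitted alone called genes for piericidin, and only replicates 3 and 4 did for antimycin (258). The counts of 0 are from edgeR, and at 1 h without the block 595, 300, 334 and 883 genes had an unadjusted p under 0.05 in the 2-group comparisons named.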
